A study of Homo sapiens with 6 samples.

How the data were processed

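Total RNA of cells labelled Hep3B was reverse-transcribed from a T7 oligo(dT) primer, amplified as antisense RNA and labelled with a cyanine dye, Cy3, per the labels' protocols, so that signal comes mainly from the 3' part of polyadenylated transcripts. The deposited table holds 1 intensity per probe and array on a linear scale. The scanner, its software, the background correction and the normalization are not given in the sources used here. The values point to background subtraction, since 3 of the 6 columns hold intensities below 0 (1330, 12 and 6 probes), and to a scaling between arrays by the authors that was not quantile normalization, since medians lay between 504 and 600 and upper quartiles between 2486 and 2618. No detection flags were used here, so the level that separates signal from background is unknown and probes are described by their percentile of mean signal. Array numbers stand for replicates as the sample titles give them.

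Intensities under 1 were set to 1, which concerned 5.35% of the probes on vector replicate 1 and under 0.1% on each other array. The log2 values were then quantile normalized. Each of the 28264 probes was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no trend), arrays labelled CCN5 minus arrays labelled vector, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. All 6 arrays entered the fit without covariates, since the labels give no other factor. For CCN5 an exact two-sided permutation test of the group means was added. A table of the platform annotation named 25893 probes with 1 gene symbol each, 0 with several, and 2371 stay unnamed here. All 25893 entrez identifiers matched the RefSeq gene table of GRCh38.p14, which was used for names only. A gene with several probes was represented by the brightest one, which gave 19090 genes, and probes of named genes that differed in sign are stated.

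Before the data were examined, 36 gene lists with 739 members were fixed from the treatment and the cell line named in the labels, of which 689 members were measured. Each list was tested with limma's camera, which compares the list with all other genes, at a preset correlation of 0.01, with adjustment over the 36 lists, and counts adjusted over the list alone are given beside it. The rule for named genes was set at the same time: the CCN family, the 12 genes with the largest rise and fall among those past the threshold (as none passed, the 12 with the smallest p in each direction) and up to 4 members of each described list. Random lists of matched signal (10000 draws) gave a percentile for each list's median.

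The alternatives were the deposited log2 scale, median centring, log2(value + 50), leaving out the dimmest 25% or 50% of probes, a trended and robust variance, array weights, the replicate number as a block, 1 probe per gene, the mean of a gene's probes, a log2 difference of at least 1, an adjusted threshold of 0.01, a plain equal-variance test, an estimated correlation, fry, and leaving out each array in turn. Added after seeing the data were 5 gene lists, 266 families of gene symbols, 24 chromosomes and the signal levels of marker lists. Simulated arrays were made from the real means and spread, with independent noise per probe. All simulated changes of single probes were placed in the brighter 50% of probes, so recovery on dim probes is unknown. Tested over all 28264 probes, limma recovered 10.4% of changes of 0.5 on the log2 scale, 79.1% of 1 and 98.5% of 2, with 8 false calls. Over the brighter 14132 probes it recovered 52.2%, 95.5% and 98.5%, with 3 false calls. A simulated list of 25 genes shifted by 0.3 gave a camera p of 9.39e-19 and an unshifted one 0.793. As simulated genes varied independently of one another, these values do not test the preset correlation on lists of correlated genes. Figures were drawn with matplotlib 3.10.9.

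Between pairs of arrays of one label Pearson's r over the brighter 50% of probes was 0.981 to 0.994, and between labels 0.977 to 0.987. These are correlations across probes, which are not independent replicates. The first principal component (39.7% of the variance) separated the labels, with CCN5 replicate 2 nearest to the arrays labelled vector, and the second took 27.0%.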

Results

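The series holds 6 single-colour Cy3 expression arrays of human cells labelled Hep3B, an established line derived from a hepatocellular carcinoma. By their labels, the cells of 3 arrays had been transfected with a vector, which the sample titles name GFP, and those of 3 with CCN5, a secreted matricellular protein of the CCN family also known as WISP2. Each array gave an intensity for 28264 probes, with a median of 504 to 600 and an upper quartile of 2486 to 2618. The comparison asks which transcripts differed between the cells labelled as given CCN5 and those labelled as given the vector. No array of untransfected cells is in the series, so a fall in one group cannot be told from a rise in the other. Fell and rose below are relative to the vector label. The labels do not say that the 3 replicates of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

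CCN5 signal was not raised in the arrays labelled CCN5. The single CCN5 probe read an intensity of 851 ± 25.7 (SD, n = 3) in the arrays labelled vector and 655 ± 30.7 (SD, n = 3) in those labelled CCN5. On the normalized log2 scale the difference was -0.34 (SE 0.09, 95% interval -0.56 to -0.13), a 1.27-fold higher normalized signal with the vector label. All 3 arrays labelled CCN5 lay below all 3 labelled vector, which gave an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 allow, and limma's adjusted p over all probes was 0.151. The probe's position relative to the transfected sequence is not given in the sources used here, so it may check nothing about the transfection. Because the signal ran against the labels, groups are called arrays labelled CCN5 and arrays labelled vector, a name such as CCN5 replicate 2 gives an array's label only, and every direction that follows rests on the labels alone. Of the other CCN genes, the log2 difference was 0.61 (SE 0.18) for CCN3, 0.04 for CCN1, 0.01 for CCN2, -0.09 for CCN4 and 0.10 for CCN6, and none passed the test over all probes. When adjusted over the list alone, CCN3 and CCN5 passed (0.0402 each). CCN3 lay at percentile 27.7 of signal, and CCN6 at 4.67. As deposited, CCN3 read 146.40 on vector replicate 2 and 146.36 on CCN5 replicate 2, so its labels were separated only after normalization. The sign for CCN1, CCN2 and CCN6 turned when 1 array was left out, and that of CCN2 and CCN6 also under another scale, while the 2 probes of CCN4 differed in sign.

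**Figure D1:**
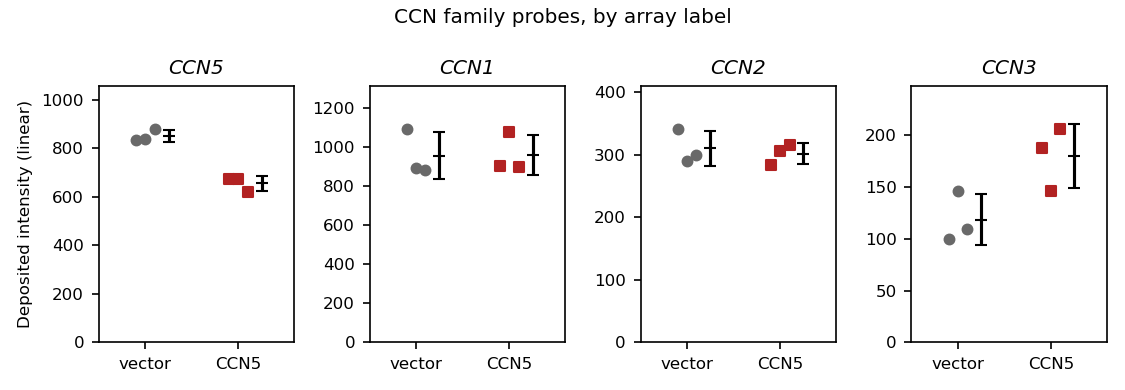
Deposited linear intensity of the CCN5, CCN1, CCN2 and CCN3 probes on each array, by label (circles, vector; squares, CCN5), with the group mean and SD beside the points (n = 3). The CCN5 probe averaged 851 with the vector label and 655 with the CCN5 label, and none of the 4 genes passed limma's test over all probes.

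No single gene passed the test over all probes, and the genes with the smallest p differed by 1.52-fold to 3.42-fold. Among the 12 genes of smallest p that were higher in the arrays labelled CCN5, the largest differences were those of MTRNR2L4 (log2 difference 1.77, SE 0.19), PLA2G2E, a secreted phospholipase A2 (1.45, SE 0.15), and the P-type ATPase genes ATP10B (1.44, SE 0.21) and ATP13A4 (1.34, SE 0.19). They were followed by HMGB1, a chromatin protein (0.98, SE 0.10), the importin IPO4 (0.79), the mitochondrial carbonic anhydrase CA5A (0.77), CLEC1B (0.75), TASOR2 (0.70), the imprinted gene PEG10 (0.68), the spindle protein DLGAP5 (0.62) and the cohesin acetyltransferase ESCO2 (0.60). Among the 12 of smallest p that were lower, the largest differences were those of PMEPA1, a TGF-beta-induced membrane protein that restrains SMAD signalling (-1.65, SE 0.15), the membrane serine protease TMPRSS4 (-1.49, SE 0.17), PLA2G3 (-1.45, SE 0.17), SAT1, the rate-limiting enzyme of polyamine catabolism (-1.21, SE 0.10), QPRT of NAD synthesis (-1.16, SE 0.11) and AMTN (-1.01, SE 0.10). SPAG4 (-0.90), FANK1 (-0.83), FAM210B (-0.80), TRAPPC6A (-0.77), the tight-junction claudin CLDN4 (-0.76) and MMEL1 (-0.74) completed these 12.

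For each of these 24 genes the 3 arrays of one label lay beyond the 3 of the other on the normalized scale, though the deposited intensities of CLEC1B and PLA2G3 overlapped, and limma's adjusted p lay between 0.0903 and 0.0977. As deposited, PLA2G3 read 9.97, 58.7 and 45.5 on vector replicates 1 to 3. On CCN5 replicates 1 to 3 it read 10.96, 23.6 and 27.8. Vector replicate 1 thus lay below all 3 arrays labelled CCN5, so the size and rank given for PLA2G3 rest on the normalization. CLEC1B, PLA2G3 and MMEL1 lay below the 25th percentile of signal. Among the largest rises, MTRNR2L4 lay at percentile 32.0, ATP10B at 27.5 and ATP13A4 at 25.3, against 66.4 for PLA2G2E. A second, dimmer probe gave -0.0041 for PEG10, -0.05 for ATP13A4 and -2.09 for ESCO2. For SAT1 (-0.52), TMPRSS4 (-0.39) and TRAPPC6A (-0.62) the second, dimmer probe kept the sign with a smaller difference. With limma over all 28264 probes, 0 were higher and 0 lower at an adjusted p under 0.05, against 2437 higher and 2934 lower at an unadjusted p under 0.05. Chance gives 1413 in all on average. As probes vary together, a single grouping can stray far from that, and other splits of the 6 arrays gave 405 to 2057. A plain equal-variance test per probe called 0 and 2. The count depended on the dim probes and the variance model. Without the dimmer 50% of probes limma called 432 higher and 567 lower of 14132, among them 6 of the 12 higher and 9 of the 12 lower genes named, the others having been left out with the dim probes. With an intensity-dependent, robust variance it called 188 and 336.

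**Figure D2:**
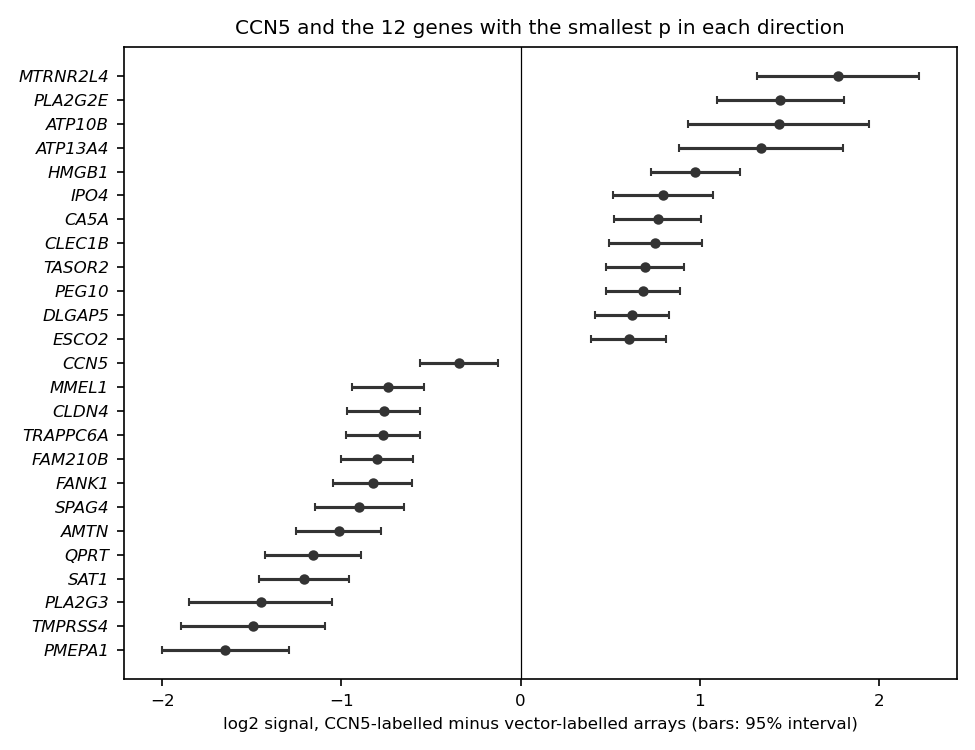
Log2 difference, arrays labelled CCN5 minus arrays labelled vector, with its 95% interval, for CCN5 and for the 12 genes of smallest p in each direction (n = 3 arrays per label). The differences run from -1.65 for PMEPA1 to 1.77 for MTRNR2L4, and none passed the adjusted threshold over all probes.

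Interferon-response genes fell together in the arrays labelled CCN5. Of 26 measured members 24 were lower, with a mean log2 difference of -0.33 and a median of -0.31, and 13 were lower when adjusted over the list alone, against 0 over all probes. IFI27 differed by -1.33 (SE 0.16) and OASL, an oligoadenylate synthetase-like antiviral protein, by -0.56 (SE 0.09). The list passed limma's camera test at an adjusted p of 1.83e-07 over 36 lists (adjusted p = 0.110 with an estimated correlation). The leukocyte markers, which did not pass, moved the same way, with 11 of 13 lower and a median of -0.34 (adjusted p 0.0705). Most of these markers were dim, 10 of the 13 lying below the 50th percentile of signal over all probes. Antigen-presentation genes fell as well, with 12 of 17 lower and a mean of -0.18 (adjusted p 0.0216, and adjusted p = 0.330 with an estimated correlation). Only 1 member of that list, the class I gene HLA-F (-0.79, SE 0.13), passed when adjusted over the list alone, and HLA-E stood at -0.38 (SE 0.10). Other, dimmer HLA-F probes gave -0.42 and -0.37. NF-kB targets, cytokines and chemokines had 20 of 23 members lower and a mean of -0.15 (adjusted p 0.0192, and adjusted p = 0.329 with an estimated correlation). In that list 2 members were lower when adjusted over the list alone, and the cytokine IL1B differed by -0.49 (SE 0.10) and NFKB2 by -0.37 (SE 0.09), with a second NFKB2 probe at 0.13. The antigen-presentation call was lost without vector replicate 2 (adjusted p 0.0607), vector replicate 3 (0.0562) or CCN5 replicate 2 (0.175), and the NF-kB call without vector replicate 2 (0.0607) or CCN5 replicate 2 (0.175).

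Immediate early and MAPK feedback genes also fell, with 20 of 24 members lower and a mean of -0.27 (camera adjusted p 0.00284, and adjusted p = 0.329 with an estimated correlation). When adjusted over the list alone 5 members were lower and 2 higher. The members of smallest p were both lower. The ERK-induced transcription factor ETV5 differed by -0.82 (SE 0.09) and the ERK phosphatase DUSP6, at percentile 30.2 of signal, by -0.91 (SE 0.12). Without the dimmer 50% of probes that list missed the threshold (adjusted p 0.0559). Among matrix proteases and inhibitors 14 of 20 members were lower, with a mean of -0.22 (adjusted p 0.0192, and adjusted p = 0.330 with an estimated correlation) and 4 lower when adjusted over the list alone. The urokinase gene PLAU stood at -0.97 (SE 0.12) and the collagenase MMP13 at -0.81 (SE 0.11). Cholesterol synthesis genes fell with a mean of -0.18, 13 of 18 being lower and 4 lower when adjusted over the list alone (adjusted p 0.0192, and adjusted p = 0.329 with an estimated correlation). IDI1 differed by -0.68 (SE 0.12), with a second probe at 0.03, and EBP by -0.42 (SE 0.11). The protease call was lost without vector replicate 2 (adjusted p 0.0607) or CCN5 replicate 1 (0.0639), and the cholesterol call without vector replicate 3 (0.0504) or CCN5 replicate 2 (0.175).

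Cell-cycle genes rose in the arrays labelled CCN5. Of 24 measured G2 and mitosis genes 21 were higher, with a mean log2 difference of 0.27 and a median of 0.32, and 12 were higher when adjusted over the list alone, against 0 over all probes. The mitotic kinase PLK1 stood at 0.44 (SE 0.09) and the centromeric histone CENPA at 0.52 (SE 0.11), with a second CENPA probe at 0.13. The list passed camera at an adjusted p of 1.46e-07 (adjusted p = 0.329 with an estimated correlation), and its unadjusted camera p, 4.05e-09 for the labelled groups, was 3.29e-06, 1.39e-05 and 0.00769 in the 3 splits that put vector replicate 1 with 2 of the arrays labelled CCN5. DNA replication and S phase genes were higher for 18 of 24 members with a mean of 0.18, 4 of them when adjusted over the list alone (adjusted p 0.00128, and adjusted p = 0.329 with an estimated correlation). The origin-licensing factor CDC6 differed by 0.54 (SE 0.11) and UHRF1, which maintains DNA methylation, by 0.40 (SE 0.08). Heat shock and chaperone genes rose with a mean of 0.19, 15 of 17 being higher and 4 higher when adjusted over the list alone (adjusted p 0.00128, and adjusted p = 0.261 with an estimated correlation). The inducible chaperone HSPA1A stood at 0.55 (SE 0.10) and its partner DNAJA1 at 0.60 (SE 0.11). YAP/TEAD targets had 14 of 18 members higher and a mean of 0.16, with 2 higher when adjusted over the list alone (adjusted p 0.0170, and adjusted p = 0.329 with an estimated correlation). NT5E, an ectonucleotidase, differed by 0.69 (SE 0.13) and tissue factor, F3, by 0.50 (SE 0.10). The list also holds CCN1 and CCN2, which stood at 0.04 (SE 0.15) and 0.01 (SE 0.18). The YAP/TEAD call was lost without vector replicate 2 (adjusted p 0.0535) or CCN5 replicate 2 (0.0758).

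**Figure D3:**
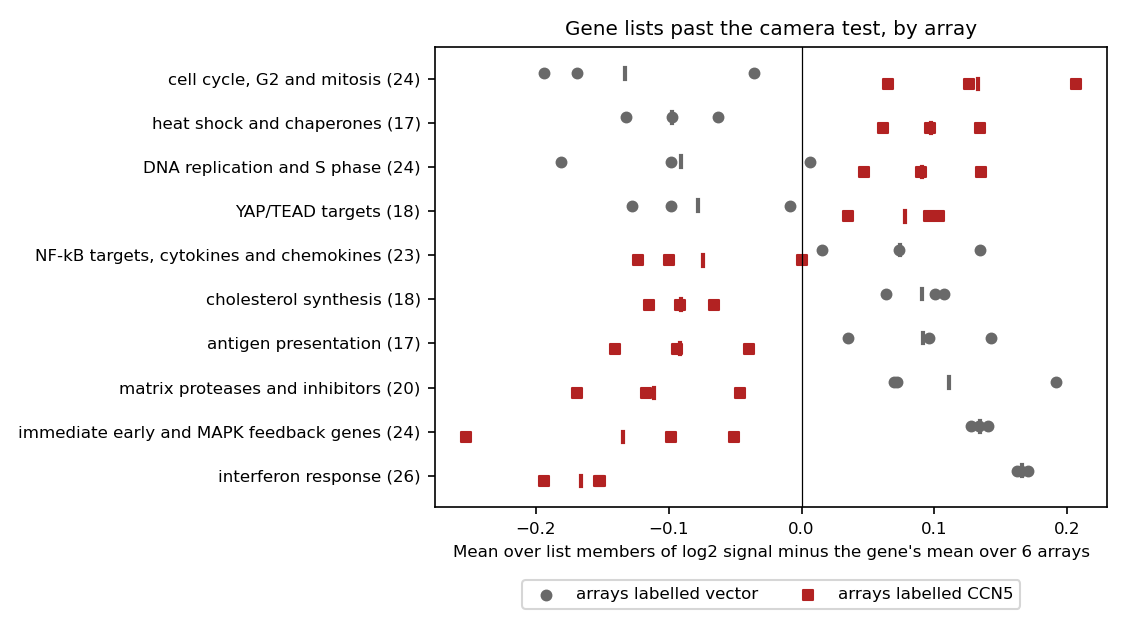
Mean over the members of each of the 10 gene lists that passed camera, of the log2 signal minus the gene's mean over the 6 arrays, per array (circles, vector label; squares, CCN5 label; short lines, group means; members measured in brackets). The arrays labelled CCN5 lie to the right for 4 lists and to the left for 6, and 0 of the 10 calls were kept with an estimated correlation.

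The other 26 lists did not pass camera. Liver genes showed no shift past the threshold. Secreted liver proteins had a mean of -0.11 (adjusted p 0.270) with APOE at -0.61, and 20 of their 23 probes lay below the 50th percentile of signal over all probes. Hepatocyte transcription factors had a mean of -0.08 (adjusted p 0.377), fetal liver and stem-like hepatoma genes -0.04 (0.933), bile acid and drug metabolism -0.13 (0.266) with CYP3A5 at -0.73, acute phase proteins -0.12 (0.291) with complement C3 at -0.59 and a second, dimmer C3 probe at 0.003, and growth factors and receptors in hepatoma -0.12 (0.214) with IGF1R at -0.42. Dimmer probes gave -0.35 and -0.28 for CYP3A5 and -0.03 for IGF1R. Collagens and matrix had a mean of -0.12 and a median of -0.23 (adjusted p 0.0521), with LUM at -0.55 and a second, dim LUM probe at 0.68. For mesenchymal and EMT genes the mean was -0.11 and the median -0.20 (0.0891), with the membrane collagenase MMP14 at -0.78. For integrins and focal adhesion the mean was -0.09 and the median -0.002 (0.333), with ITGA2 at -0.86 and a second, dimmer ITGA2 probe at -0.42. The epithelial junction list had a mean of 0.12, a median of 0.03 and a downward camera direction (0.614), with the keratin KRT19 at -0.46. Its mean held the desmosome gene DSP, named after its values were seen, at 3.36 with an SE of 2.87. Wnt/beta-catenin targets had a mean of -0.03 (adjusted p 0.544) with MYC at 0.38 and AXIN2 at -0.35, TGF-beta targets -0.08 (0.372) with BHLHE40 at -0.74, and the CCN family 0.05 (0.992), against a median of 0.03.

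Metabolic and stress lists gave means of -0.13 for fatty acid synthesis and storage (adjusted p 0.0792), with FADS1 at -0.44, -0.08 for fatty acid oxidation and ketogenesis (0.314), with CPT2 at -0.44, and -0.17 for hypoxia and glycolysis (0.152), with PFKFB4 at -0.85 and ALDOC at -0.90. The unfolded protein response stood at -0.11 (adjusted p 0.131) with CRELD2 at -0.52, and NRF2 and metallothioneins at 0.02 (0.754), with MT1X at -0.66 and HMOX1, the haem oxygenase, at 0.75. CDK inhibitors and p53-linked genes had a mean of -0.06 (adjusted p 0.439), with CDKN1A at -0.68 and PLK2 at 0.48, and apoptosis regulators -0.07 (0.314), with XIAP at -0.34. Ribosomal proteins (0.04, adjusted p 0.439), nuclear-encoded oxidative phosphorylation (-0.04, 0.647) and housekeeping controls (0.10, 0.174) did not pass either. Of the markers of other cell types, leukocyte markers had a mean of -0.22 with 11 of 13 members lower (adjusted p 0.0705), fibroblast markers -0.12 (0.152) and endothelial markers -0.06 (0.543). The macrophage gene CD68 stood at -0.41, CSF1R at -0.53, S100A4 at -0.54 and PECAM1 at -0.39. Under median centring or on the deposited scale the mean turned above 0 for 11 of the lists, while the median of all probes moved to 0.078 and 0.034, and all of these means but those of the fibroblast markers (0.081 and 0.037) stayed below that median. For 4 lists the sign turned when 1 array was left out.

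When adjusted over the list alone, some members of uncalled lists passed, against 0 over all probes. Mesenchymal and EMT genes had 5 lower, acute phase proteins 4 lower, fibroblast markers 3 lower and fatty acid synthesis and storage 1 lower. TGF-beta targets, collagens and matrix, integrins and focal adhesion, secreted liver proteins, endothelial markers and leukocyte markers had 2 lower each. Members passed in both directions in the lists of CDK inhibitors and p53-linked genes (3 higher, 4 lower), NRF2 and metallothioneins (3 higher, 3 lower), hypoxia and glycolysis (1 higher, 4 lower) and epithelial junction genes (1 higher, 3 lower). The CCN family, Wnt/beta-catenin targets, fetal liver and stem-like hepatoma genes and bile acid and drug metabolism each had 1 higher and 1 lower. In the other 8 uncalled lists 0 members passed when adjusted over the list alone.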

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

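The added tests of other gene groups and levels, described under the other observations, were chosen after seeing the data; the settings here were planned. CCN5 stayed lower under every setting (-0.38 to -0.30; adjusted p 0.0486 to 0.449) and passed the threshold without the dimmer 50% of probes (-0.34). Probes higher and lower numbered 33 and 151 without the lowest 25%, 432 and 567 without the lower 50%, 188 and 336 with a trended, robust variance, 59 and 180 with log2(value + 50), and 0 and 2 with a plain test; without 1 array, higher probes numbered 0 and lower ones 0 to 1. The calls of the lower-50% and robust settings shared 444 probes. Fewer tested probes and a larger prior df (4.33 against 2.46) go with the first of these; other causes were not tested. All 10 called lists kept their direction in every setting. Lists called numbered 0 with an estimated correlation, 20 by fry, which does not compare lists with other genes, and 6 to 13 without 1 array. Whether the replicate numbers pair the arrays cannot be told from 3 arrays per label. Same-number deviations correlated at -0.14, 0.12 and 0.02. Of the arrays labelled vector only vector 2 correlated best with its own number (1 and 2 with CCN5 2, 3 with CCN5 1). The replicate block gave 0 probes higher, 0 lower, 11 lists and -0.34 for CCN5. Reversed, all uncalled: CCN2 at -0.036 as deposited and CCN6 at -0.036 with log2(value + 50); on the deposited scale secreted liver proteins 0.024, hepatoma growth factors 0.030, oxidative phosphorylation 0.014, fibroblast 0.037 and endothelial markers 0.025; under median centring the same lists 0.069, 0.075, 0.059, 0.081 and 0.069, and Wnt 0.015, TGF-beta 0.020, collagens 0.029, fetal liver 0.019, bile acid 0.026 and acute phase 0.019; NRF2 -0.020 without the lowest 25% and -0.021 without the lower 50%. Without 1 array CCN1 ran from -0.058 to 0.16, CCN2 from -0.083 to 0.17, CCN6 from -0.11 to 0.35, the CCN family from -0.0049 to 0.15, epithelial junctions from -0.092 to 0.24, NRF2 from -0.018 to 0.069 and endothelial markers from -0.12 to 0.016. The cause of these was not tested. The median of all probes moved from -0.0047 to 0.078 under median centring and 0.034 as deposited, and of the list means that turned on these scales only those of the fibroblast markers lay above it. Without detection flags, how far dim probes lie over background is unknown.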

Other observations

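Every test in this part was chosen after the results were seen: the added gene groups, the level percentiles, the splits and the explanations weighed. Ribosome biogenesis factors were higher for 28 of 30 members in the arrays labelled CCN5, with a mean log2 difference of 0.31 and 12 higher when adjusted over the list alone (limma's camera, adjusted p 7.5e-09 over 9 added tests, and adjusted p = 0.120 with an estimated correlation). Of that list BOP1, NIP7, RBM19 and the family of its RNA polymerase I genes had been seen first. Without them the mean was 0.26 with 23 of 24 higher (adjusted p 1.97e-06, and adjusted p = 0.120 with an estimated correlation), RRP12 at 0.47 (SE 0.11) and NOP58 at 0.50 (SE 0.13). Spliceosome components had a mean of 0.12 with 26 of 34 higher (adjusted p 0.000517, and adjusted p = 0.120 with an estimated correlation), and without the SF3 genes, seen first, 0.09 with 19 of 25 higher (adjusted p 0.00844, and adjusted p = 0.120 with an estimated correlation). The TIMM genes of mitochondrial protein import alone passed among 266 symbol families, with 13 of 14 higher and a median of 0.22 (adjusted p 0.0253, and adjusted p = 0.876 with an estimated correlation). A protein import list made after that had 25 of 28 members higher and a mean of 0.18, which is no separate evidence, and its 5 members not seen first had a mean of 0.12 and did not pass (adjusted p 0.137).

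Lysosomal proteins were lower for 21 of 29 members with a mean of -0.13 (adjusted p 0.0280, and adjusted p = 0.154 with an estimated correlation), with the cholesterol transporter NPC2 at -0.42 (SE 0.08). FOXO and quiescence-linked genes had a mean of -0.21 with 15 of 20 lower (adjusted p 0.0170, and adjusted p = 0.120 with an estimated correlation), YPEL5 at -0.63 (SE 0.08) and YPEL3 at -0.94 (SE 0.14). Without TXNIP and KLHL24, seen first, that list stood at -0.14 and did not pass (adjusted p 0.0966). None of 24 chromosomes passed (smallest adjusted p 0.993, 0 at an unadjusted p under 0.05).

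Most genes of secreted liver proteins were dim on all 6 arrays and many genes of squamous epithelium were bright. Hep3B cells are known to make AFP, yet ALB read 30.9 to 84.9 and AFP 99.3 to 183, and the 23 secreted liver proteins had a median level percentile of 24.4 to 29.7 per array. SERPINC1 (percentile 73.3), HPX (65.9) and APOC3 (64.2) were the brightest of them. Other liver genes were mixed, as bile acid and drug metabolism ran from CYP7A1 at percentile 7.53 to CYP1A2 at 98.8. Of 33 measured squamous epithelial markers, 13 of them picked after they were seen, 18 lay above the 90th percentile, with 7 of the 20 not seen first above the 90th and 5 below the 50th; the brightest were S100A2 (357602 to 409044), LY6D (115942 to 157764) and MIR205HG (80532 to 123172), with KRT5 at 37102 to 67547, and the fixed integrin list also holds 2 of them, while intestinal and melanocyte markers had medians of 22.1 and 31.3 and hepatocyte transcription factors 58.3, percentiles that only describe since probes differ in response. Probe names shuffled throughout would make the interferon list a random one, and its median difference lay at percentile 0 of 10000 matched random lists. Nor would shuffled names place ribosomal proteins at a median level percentile of 99.5, with 18 of 21 above the 90th. Both argue against shuffling throughout but not against wrong names for some probes. Liver probes that do not respond stay open, since 20 of 23 lay below the 50th percentile and no array of liver RNA was used here. RNA from squamous-type epithelial cells in place of hepatoma cells may be a source. Over all 33 squamous markers the per-array median was 94.0 to 96.8, but 13 of them were picked after they were seen. Over the 20 not seen first it was 70.7 to 75.6. The lowest lay short of the 75 set for this source and above the 50 set against it. Both limits were set after the levels were seen, so the miss is not evidence against this source. This too stays open, and no biological explanation was tested.

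CCN5 signal was lower where the label names CCN5. If the probe read the transfected transcript under right labels, a rise of at least 1 on the log2 scale was assumed, and the upper 95% limit of the difference was -0.13; under exchanged labels the upper limit of the opposite difference was 0.56, also short of 1. Both argue against a strongly raised transcript that the probe reads, in either group. The probe may lie outside the transfected sequence, which its level at percentile 55.2 does not settle without a probe sequence, and a weak or absent transfection was not tested apart from it. A lower level of the cells' own CCN5 transcript stays open as an untested biological explanation.

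The lower interferon and higher mitosis lists were set against a trend with signal level and against a single array. Among 10000 random lists matched on level their medians lay at percentiles 0 and 100, and the mean shifts nearest 0 with 1 array left out were -0.32 and 0.23, which argues against both explanations. A difference in culture or handling between the labels may still be behind the shifts, since the labels name no batch and none was tested. An effect of the transfected CCN5 stays open and untested. Without untransfected cells, a shift in the arrays labelled vector cannot be told from one in those labelled CCN5.

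The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 0 probes and the highest other 2, so that all 10 gave as many. Without the lower 50% of probes it called 999 against 8 in the highest other, at an unadjusted p under 0.05 it gave 5371 against 2057, and it called 10 lists against 5, with 1 split as large in each of these. The mitosis list, at an unadjusted camera p of 4.05e-09 in the real split, gave 3.29e-06, 1.39e-05 and 0.00769 in the 3 splits that put vector replicate 1 with 2 arrays labelled CCN5, and the interferon list, at 1.02e-08, reached 0.000501. Groups did not overlap for 7513 probes (26.6%, where chance gives 10% on average for 3 against 3, with a wide spread as probes vary together).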
